A study of Mus musculus with 49 samples.

How the data were processed

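Drop-seq captures single cells in droplets with barcoded beads, so that each RNA molecule carries a cell barcode and a unique molecular identifier (UMI). It was applied to cells of hearts from mice at postnatal day 0, dissociated with trypsin, per the labels' protocols. The series holds 49 libraries from 7 biological samples. These are 3 right atria, 1 left atrium, 1 remainder without the right atrium, 1 remainder without either atrium and 1 whole heart. The labels number several technical libraries within each biological replicate, so the libraries of a replicate were summed and the biological replicate was the unit of every test. The labels give 1 internal sample number for all 3 right atria, while library names within right atrium 3 and within the whole heart carry 2 different numbers each. Which samples come from separate hearts or litters is therefore open, and with it what n and SD cover. Xist, expressed in females, and the Y-linked Ddx3y stood at 204 to 496 and 41.2 to 70.3 CPM across the 7 samples. RNA of both sexes in every sample argues against any sample being 1 heart. A sample named below as an atrium, a remainder or a heart can therefore be a pool of animals. For 1 library of the remainder without the right atrium, the name carries the number of right atrium 2 and the barcodes that of the remainder. It was kept with the remainder, whose 6 libraries held 45.8% to 49.0% ventricular cardiomyocytes.

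The deposited values are raw counts per gene and cell barcode, with no normalization. Per the submitters' processing notes, bcl2fastq 2.17.1.14, STAR 2.5.3a, UMI-tools and featureCounts 1.5.3 were used with build mm10. The notes give no order of steps, no annotation release and no strand setting, so reads from overlapping genes on opposite strands could not be told apart. Genes named below that overlap another gene are uncertain for this reason, among them Ryr3 (Aven), Pln (Cep85l), Myl3 (Pth1r), Fabp3 (Zcchc17), Timp4 (Syn2) and Kif20a (Cdc23). The deposited files hold 15684 barcodes, each with at least 200 genes, and 27999 gene identifiers, of which 27645 matched a gene symbol and 354 did not. A row for EGFP had a count in 0 of 15684 barcodes, and 13 mitochondrial genes took 4.85% of all counts. In 10 pairs of libraries from the same biological replicate more barcodes were shared than chance gives (p threshold 0.001), and these barcodes were summed, which removed 26. Coordinates are given for mm10 from the reference gene table.

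Cells were kept with at least 500 UMIs, at least 300 genes and at most 50% mitochondrial counts, which removed 982 of 15658. Scrublet, run per library in scanpy 1.11.5, called 195 doublets (1.33%), which were removed, and 14481 cells remained with a median of 2179 UMIs. Counts were scaled to 10000 per cell and log-transformed. Clustering used 2000 variable genes seen in at least 5 cells, with scaled values limited to 10, then 30 principal components, 15 neighbours and Leiden resolution 1.0 (igraph 0.11.9), with no integration. The transcription factor list, the proliferation list, mitochondrial, ribosomal protein and sex-linked genes were left out of the clustering genes, while other genes that vary with them stayed in. The 21 clusters were named from marker genes as the class with the highest score. The score was the markers' mean log2 level in the cluster minus that over all clusters (pseudocount 10 CPM). A name needed a score of at least 1.5, a score of the next class of at most 0.6 of it, and 3 markers raised 2-fold over the other cells. The 10 genes most raised in a cluster could not hold more markers of other classes than of its own. Shallow clusters with none of their own markers among those 10 stayed unnamed. Atrial and ventricular names needed a gap of 1.0 between their scores. The markers were fixed in advance, and these scoring limits were set after the markers' levels were seen. Of the 21 clusters, 2 stayed unnamed (390 cells), and the others gave 10 classes, named below without the suffix "-like" that each carries, since all rest on markers alone.

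Counts were summed per biological sample, and per sample and class where at least 20 cells were present. Sums were tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, two-sided, filterByExpr by region, TMM normalization). Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05, and levels from these fits are TMM-normalised CPM. Plain CPM were used for the genes that split the libraries below, for Xist, Ddx3y, Scgb1a1 and Tfap2a, and for sums of dissociation response genes. They were also used for Malat1 in fibroblasts and for Malat1 and mt-Co1 in atrial cardiomyocytes alone. Region comparisons were fitted over all 7 samples with region as the only term, and both remainders formed 1 group. The remainders are different dissections, with the left atrium kept in 1 of them (5.58% against 0.388% atrial cardiomyocytes). Their SD and their part of the spread in the tests therefore include that difference. The lone left atrium and the lone whole heart add nothing to the estimate of the spread and are assumed to vary like the other groups. Endothelial and endocardial cells were summed together, as were all cardiomyocyte classes. Class comparisons set each class seen in at least 4 samples against the mean of the other classes, with the biological sample as a block. A gene counted as above background only where its mean CPM in the class reached that in the sums over all cells of the region where it was higher, since free RNA enters every droplet. Genes with the largest change were named in fibroblasts and endothelial cells only where above background. Class shares were compared with a two-sided exact permutation test.

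Of 19 gene lists, those described cover transcription factors, atrial, ventricular, pacemaker and conduction, sarcomere, oxidative phosphorylation, glycolysis, fatty acid metabolism, proliferation, extracellular matrix, retinoic acid and chamber position, endocardial, capillary and coronary endothelial, dissociation response, hypoxia and hemoglobin genes. They were tested with camera (limma 3.58.1) with its preset correlation, camera with an estimated correlation, and fry, adjusted over lists and comparisons. The lists, markers, tests and the rule for named genes were chosen before the data were examined. By that rule, genes named in a region comparison had an adjusted p under 0.05, an absolute log2 fold change of at least 1, a mean of at least 20 CPM and no overlap between the samples of the groups compared. The 10 with the largest change in each direction were taken, without predicted, mitochondrial, hemoglobin or sex-linked genes. Up to 4 members per list with the smallest adjusted p were named as well, and up to 4 transcription factors per class with the largest log2 fold change.

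The libraries fall into a first set of 28 and a second set of 21, which the labels do not mention. They were split at 500 CPM for the sum of 5 genes (Rpl24, Rpl10, Ppia, Gapdh and 1 not reported here). That sum reached at most 172 CPM in the first set and at least 1002 CPM in the second. All libraries of both remainders and of the whole heart are in the first set, while each atrium has libraries of both sets. The left atrium has 1 library in the first set and 4 in the second. Right atria 1, 2 and 3 have 1, 7 and 5 libraries in the first set and 5, 1 and 11 in the second. Within the 4 atrial samples, 313 of 8326 genes tested differed between the sets, 155 of them higher in the second. Genes of this kind are called library-set genes below. After they were seen, the top 10 was also taken without them, and every region comparison was repeated in the first set alone.

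Alternatives covered DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, a minimum of 1000 UMIs, at most 20% mitochondrial counts, doublets kept, Leiden resolutions of 0.5 and 2.0, thinned counts, each biological sample left out in turn and the left atrium added to the remainders. Further alternatives chosen after the data were seen were the first or second library set alone, library-set genes left out, barcodes sharing 11 bases merged, clustering without the protocadherin and Ugt1a gene families, endocardial cells alone and a cardiomyocyte cluster left out. The procedures were tested on simulated counts with 200 changed genes. For cardiomyocytes, run on 11800 genes, 83% of the 4-fold and 20% of the 2-fold changes were recovered, with 8 of 111 calls false. For fibroblasts, run on 11085 genes, 63% and 4% were recovered, with 9 of 76 calls false. For endothelial cells, run on 11330 genes, 68% and 15% were recovered, with 13 of 96 calls false. For left against right atrial cardiomyocytes, run on 11839 genes, 54% and 6% were recovered, with 3 of 63 calls false. Over all cells, run on 14733 genes, 75% and 6% were recovered, with 16 of 97 calls false. For left against right over all cells, run on 14734 genes, 52% and 5% were recovered, with 8 of 65 calls false. For a class against the others, run on 7375 genes, 85% and 79% were recovered, with 12 of 176 calls false. The share of false calls was above the adjusted p threshold in all of these except left against right atrial cardiomyocytes. Called genes in those comparisons can therefore include more false ones than the threshold implies. Intervals given for shares are exact Clopper-Pearson 95% intervals, and intervals and floors (3 counts) cover counting error only.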

Results

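Drop-seq profiles were collected from hearts of newborn mice (postnatal day 0, mixed C57BL6 and ICR background) to build a reference map of cardiac cells, which the series says served to choose transcription factors for turning cells of one lineage into another. The pieces were the right atrium (3 biological samples, with 6, 8 and 16 technical libraries), the left atrium (1 sample, 5 libraries), the heart without the right atrium (1 sample, 6 libraries), the heart without either atrium (1 sample, 1 library) and the whole heart (1 sample, 7 libraries). The 2 samples without the right atrium are called the remainders. Right atria 1, 2 and 3 held 4278753, 6243695 and 10357454 counts in 1730, 1853 and 5544 barcodes. The left atrium held 2587903 counts in 699 barcodes and the whole heart 10873725 in 2729. The remainder without the right atrium held 16164506 counts in 2861 barcodes, and that without either atrium 1145477 in 268. Median counts per barcode ran from 1287.5 in right atrium 3 to 3936 in the remainder without the right atrium. Class shares of the left atrium and the whole heart, with 1 sample each, are given as values only.

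Which cell classes make up each piece was asked first. Atrial cardiomyocytes made up 50.4% ± 8.13 of right atrial cells (SD, n = 3) and 2.99% ± 3.67 of the remainders (n = 2). Ventricular cardiomyocytes made up 0.450% ± 0.429 and 46.8% ± 0.992. Endocardial cells, which line the chambers, had the second highest mean share in the right atrium (17.7% ± 3.41 against 5.68% ± 1.46), while vascular endothelial cells held 1.73% ± 0.591 there against 15.4% ± 1.24 in the remainders. Mural cells, the pericytes and smooth muscle of vessels, went the same way as the endothelial cells (0.380% ± 0.0998 against 4.82% ± 0.234). Macrophages (2.47% ± 0.696 against 1.09% ± 0.0976), epicardial cells (4.01% ± 1.72 against 1.18% ± 0.0273) and erythroid cells (3.50% ± 2.54 against 0.759% ± 0.0234) had higher shares in the right atrium. Fibroblast shares overlapped (15.9% ± 8.16 against 17.1% ± 5.43) and were above the endocardial share in right atrium 3 (24.5% against 13.9%). Shares overlapped too for the other leukocytes, led by T cell genes (0.868% ± 0.712 against 0.300% ± 0.425). Unnamed clusters held 2.54% ± 0.267 and 3.86% ± 0.0172.

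In the two-sided exact permutation test, p was 0.1 for the atrial, ventricular, endocardial, endothelial, mural and macrophage classes. It was 0.2 for epicardial, 0.3 for erythroid, 0.4 for other leukocyte and 0.9 for fibroblast cells. The 10 possible assignments allow no p below 0.1, so no share could reach 0.05. The samples of the groups did not overlap for 8 of the 10 named classes. Within the first library set alone the differences were 45.9 percentage points for atrial, -46.4 for ventricular, 12.3 for endocardial, -14.0 for endothelial and -4.52 for mural cells. All libraries gave 47.4, -46.4, 12.0, -13.7 and -4.44. Ventricular cardiomyocytes were deeper (median 4531 UMIs) than atrial cardiomyocytes (1992), endothelial (2553), fibroblast (2013) and endocardial cells (1561.5), so the minimum of 500 UMIs can weigh on these shares.

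The left atrium was led by atrial cardiomyocytes too. Of its 657 cells, 54.6% (exact 95% interval 50.7 to 58.5) were atrial cardiomyocytes, 20.1% (17.1 to 23.4) endocardial, 11.6% (9.22 to 14.3) fibroblast and 0.913% (0.336 to 1.98) endothelial cells. Ventricular cardiomyocytes were 0 of 657 cells, with an exact upper limit of 0.560%. The whole heart held fibroblasts (27.9%, 26.2 to 29.7), ventricular cardiomyocytes (22.2%, 20.6 to 23.8), atrial cardiomyocytes (19.5%, 18.0 to 21.1), endocardial cells (10.1%, 8.93 to 11.3) and endothelial cells (8.48%, 7.43 to 9.62) among 2595 cells.

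**Figure D1:**
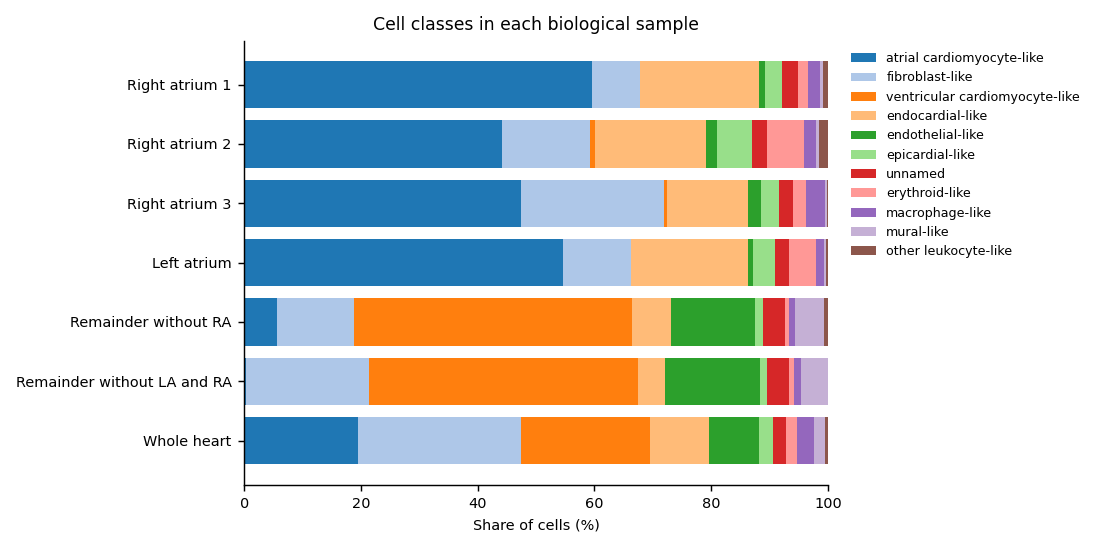
Share of cells (%) of each class in the 7 biological samples, as stacked bars. Atrial cardiomyocytes make up 44.2% to 59.6% of the right atria, and ventricular cardiomyocytes lead both remainders with a mean of 46.8%.

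Summed over all cells, the right atrium differed from the remainders by its atrial muscle, ventricular muscle, vessel and immediate-early genes. Bmp10 (ENSMUSG00000030046, mm10 chromosome 6, 87428994 to 87437677), a growth factor of the heart wall, was higher by a log2 fold change of 7.28 (SE 0.58, adjusted p = 0.000382), at 412 ± 129 CPM (SD, n = 3) against 1.60 ± 2.26 (n = 2). Sln, whose product sarcolipin restrains the calcium pump of the sarcoplasmic reticulum, rose by 4.42 (SE 0.73), and the ryanodine receptor gene Ryr3 and the myosin light chain gene Myl1 by 4.36 and 3.57. Myl2, the ventricular regulatory myosin light chain, was lower by -7.45 (SE 1.08, adjusted p = 0.00629), at 63.3 ± 67.0 against 11082 ± 3507 CPM. Ddc, an enzyme of amine synthesis, was lower by -4.63 (SE 0.29), Myh11, the smooth muscle myosin, by -4.27 (SE 0.30), and Cldn5, a tight junction protein of vessels, by -3.92 (SE 0.51).

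Other genes higher in the right atrium were Fosb (3.86), Tmem163 (3.57), Cxcl1 (3.56), Angptl7 (3.52), Cpne5 (3.46) and Gprin3 (3.39). Lower were Myl3 (-4.16), Rbp7 (-3.90), the peptide gene Apln (-3.90), Ly6c1 (-3.86), the potassium channel subunit Kcne1 (-3.65) and the uridine phosphorylase Upp1 (-3.61). Of 18 atrial genes 17 rose and 0 fell, with 17 higher and 1 lower when adjusted over the list alone (camera adjusted p = 4e-30, adjusted p = 0.129 with an estimated correlation). Of 15 ventricular genes 0 rose and 9 fell, with 0 and 11 adjusted over the list alone (camera adjusted p = 2.1e-27, adjusted p = 0.103 with an estimated correlation). Of 18 capillary and coronary endothelial genes 1 rose and 13 fell, with 2 and 15 adjusted over the list alone, among them Gpihbp1 (-3.05), Fabp4 (-3.03) and Aplnr (-2.37; adjusted p = 0.105 with an estimated correlation). Of 13 endocardial genes 4 rose and 0 fell, with 7 and 0 adjusted over the list alone, led by Npr3 (2.74), a natriuretic peptide receptor (camera adjusted p = 0.00014, adjusted p = 0.353 with an estimated correlation). Of 7 hemoglobin genes 5 rose and 0 fell, both over all genes and adjusted over the list alone (adjusted p = 0.22 with an estimated correlation), but 1 and 0 in the first library set alone. Of 25 dissociation response genes, which include the immediate-early genes, 6 rose and 0 fell, with 14 and 0 adjusted over the list alone (camera adjusted p = 4.9e-09, adjusted p = 0.433 with an estimated correlation).

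The edgeR test called 809 of 15038 genes, 355 higher and 454 lower in the right atrium, and 3172 had an unadjusted p under 0.05. Among the 10 largest increases 9 were ribosomal protein genes that belong to the library-set genes (Rps6 6.35, Rps27 5.73, Rps27a 5.41). Their log2 fold changes in the first library set alone were 0.26 to 1.32, with adjusted p from 0.16 to 0.81. The count was 39 without the remainder without the right atrium, 177 without the other remainder and 406 without right atrium 3. It was 3 with the left atrium added to the remainders and 1827 with no filter on low counts.

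Within cardiomyocytes, the comparison asked how atrial muscle of the right side differs from the muscle of the remainders, which is mostly ventricular (1345 ventricular and 158 atrial cells in the remainder without the right atrium). Bmp10 was higher by a log2 fold change of 7.38 (SE 0.59, adjusted p = 1.93e-05), at 690 ± 289 CPM (SD, n = 3) against 2.40 ± 3.39 (n = 2). Sln rose by 4.90 (SE 1.04, adjusted p = 0.00878), from 175 ± 247 to 5593 ± 2123 CPM. Myl2 (ENSMUSG00000013936, chromosome 5, 122100951 to 122113472) was lower by -7.10 (SE 0.97, adjusted p = 0.000595), at 111 ± 131 against 15178 ± 2133 CPM. Its exons overlap those of Ccdc63. Smyd2, a lysine methyltransferase, was lower by -5.83 (SE 0.28, adjusted p = 3.21e-07), at 3.53 ± 1.1 against 198 ± 24.8 CPM.

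The transcription factors that mark the chambers separated the pieces. The ventricular factors Irx4 (-6.40, SE 0.53, adjusted p = 2.24e-05) and Hey2 (-6.34, SE 0.55, adjusted p = 3.8e-05) were lower in the right atrium, as was Irx3 (-4.89, SE 0.69), which overlaps its antisense gene Irx3os. The atrial factors Nr2f2 (3.09, SE 0.32, adjusted p = 9.14e-05) and Nr2f1 (3.37, SE 0.43), and Tbx5 (2.66, SE 0.36), which acts in atrial and conduction tissue, were higher. Of 70 transcription factors 10 rose and 10 fell, with 12 and 13 adjusted over the list alone, and the list showed no shift as a set (camera adjusted p = 0.64).

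Further genes higher in the right atrium were Vsnl1 (4.83), Ryr3 (4.54), the neuropeptide Y receptor Npy1r (4.27), Gprin3 (4.23), the metal transporter Slc39a8 (4.12), Myl1 (3.89) and Cpne5 (3.78). Further genes lower there were Ddc (-4.63), Upp1 (-4.57), the lysophosphatidic acid receptor Lpar3 (-4.34), Tubb2b (-3.87) and Myl3 (-3.86). All 17 atrial genes tested rose, over all genes and adjusted over the list alone, including Angpt1 (3.55) and Stard10 (3.43), with camera adjusted p = 8.3e-39 and adjusted p = 0.103 with an estimated correlation. Of 15 ventricular genes 0 rose and 10 fell, with 1 and 12 adjusted over the list alone, including the calcium pump regulator Pln (-3.15), Kcne1 (-3.50) and Mpped2 (-6.26). Their camera adjusted p was 4e-29, with adjusted p = 0.103 with an estimated correlation. Of 18 pacemaker and conduction genes 7 rose and 0 fell, with 11 and 0 adjusted over the list alone, among them Vsnl1, the calcium channel subunit Cacna2d2 (3.61), Cpne5 and Rgs6 (2.18). For that list camera gave adjusted p = 4.9e-09, and adjusted p = 0.177 with an estimated correlation. Among 26 sarcomere genes 3 rose and 5 fell, with 3 and 7 adjusted over the list alone, as atrial Myl4 (3.08) and the slow troponin Tnni1 (-1.07) went apart (camera adjusted p = 0.018, adjusted p = 0.433 with an estimated correlation).

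Genes of energy metabolism were lower in right atrial cardiomyocytes. Of 32 oxidative phosphorylation genes 0 rose and 22 fell, with 1 and 29 adjusted over the list alone, including the cytochrome Cyc1 (-1.50) and the succinate dehydrogenase subunits Sdha (-1.53), Sdhb (-1.38) and Sdhd (-1.38). Of 22 fatty acid metabolism genes 0 rose and 18 fell, with 0 and 21 adjusted over the list alone, including the oxidation enzymes Acadm (-1.82), Hadhb (-1.71), Acadvl (-1.62) and Mlycd (-1.66). Camera gave adjusted p = 4.8e-16 and 9e-20 for these lists, and adjusted p = 0.103 and 0.177 with an estimated correlation. Of 16 glycolysis genes 1 rose and 8 fell, with 1 and 10 adjusted over the list alone, among them Eno3 (-1.18), Pkm (-1.09) and Aldoa (-1.01; adjusted p = 0.224 with an estimated correlation). The gene that rose, Gapdh (2.69), is a library-set gene with a log2 fold change of 0.02 in the first set. Of 42 proliferation genes 0 rose and 5 fell, both over all genes and adjusted over the list alone, led by Rrm2 (-1.27; camera adjusted p = 0.00024, adjusted p = 0.433 with an estimated correlation). In the first library set alone 2 fell, and 1 adjusted over the list alone. The nuclear RNA Malat1 was higher, at 21566 ± 2570 against 7607 ± 2489 CPM, and the mitochondrial mt-Co1 lower (-1.38, SE 0.35). In fibroblasts Malat1 stood at 11819 to 18969 CPM in the right atria against 4476 and 13825 in the remainders. Among atrial cardiomyocytes alone, it stood at 20354 to 25733 CPM in the right atria against 8997 in the remainder without the right atrium. In the same cells mt-Co1 stood at 1555 to 3613 against 4192 CPM. The gaps within this class rest on 1 remainder sample and do not set atrial against ventricular muscle. Malat1 and mt-Co1, which can follow the state of the cells, were chosen after their values were seen. Whether the metabolism lists follow that state too was not tested.

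Immediate-early genes, which cell dissociation can induce, moved with the pieces as well. Of 24 dissociation response genes 8 rose and 0 fell, with 9 and 0 adjusted over the list alone, including Fos (3.77), Fosb (3.72) and Egr1 (3.23), with camera adjusted p = 1e-07 and adjusted p = 0.234 with an estimated correlation. Of the 24, 1 lay above background and these 3 below it, so a change within cardiomyocytes is not shown. Of 5 hemoglobin genes 4 rose and 0 fell in cardiomyocytes, over all genes and adjusted over the list alone (adjusted p = 0.224 with an estimated correlation), also below background (Hbb-bs 485 CPM, against 3027 over all right atrial cells). Hypoxia genes went both ways, with 2 of 13 higher (Adm 3.57, P4ha1 1.38) and 1 lower (Ddit4 -1.72), the same counts adjusted over the list alone. So did extracellular matrix genes, with 2 of 33 higher and 2 lower, again the same counts adjusted over the list alone (Fbln1 3.02, Eln -2.25).

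The edgeR test called 1379 of 12082 genes, 666 higher and 713 lower in the right atrium, of which 572 and 512 changed at least 2-fold and 333 and 567 lay above background. In the first library set alone 99.55% of the called genes that could be tested there kept their sign. Among the 10 largest increases 8 were ribosomal library-set genes (Rps6 6.65, Rps27 5.91), at 0.43 to 1.54 in the first set with adjusted p from 0.086 to 0.66. The count was 580 without the remainder without the right atrium, 811 without right atrium 3 and 16 with the left atrium added to the remainders.

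**Figure D2:**
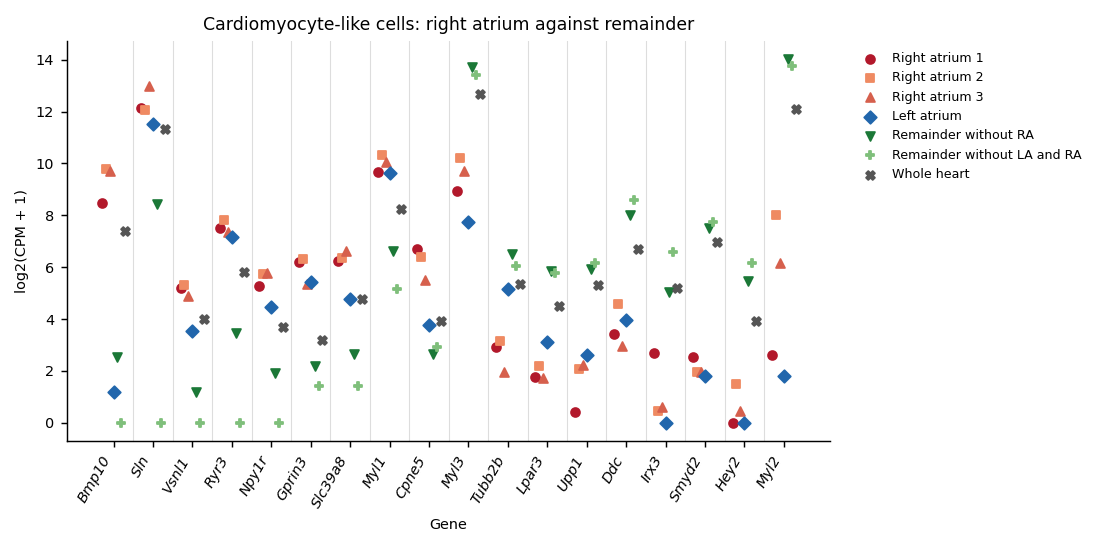
Levels in cardiomyocytes, as log2(CPM + 1), of 9 of the 10 most raised and 9 of the 10 most lowered genes in the right atrium, library-set genes left out; each point is 1 biological sample. The 3 right atria lie above both remainders for Bmp10, Sln and Vsnl1 and below both for Myl2, Hey2 and Smyd2.

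In endothelial and endocardial cells summed together, the right atrium held genes of the endocardium and the remainders genes of capillaries and coronary vessels. Npr3, an endocardial natriuretic peptide receptor, was higher by a log2 fold change of 3.01 (SE 0.39, adjusted p = 0.00105), at 1702 ± 255 CPM (SD, n = 3) against 203 ± 98.9 (n = 2). Irx5, a homeobox factor, was higher by 3.24 (SE 0.43, adjusted p = 0.00112), at 51.2 ± 4.22 against 4.95 ± 0.714 CPM. The fatty acid transporter Cd36 was lower by -3.23 (SE 0.33, adjusted p = 0.000208), at 254 ± 62.4 against 2397 ± 392 CPM, and the capillary carbonic anhydrase Car4 by -4.73 (SE 0.46, adjusted p = 0.000208), at 4.41 ± 3.89 against 137 ± 20.6 CPM. The mix of cells differed, since the 3 right atria held 335, 310 and 674 endocardial cells (cluster 13) and 18, 30 and 110 endothelial cells (cluster 11), against 12 and 190 endocardial and 42 and 411 endothelial cells in the remainders.

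Other genes higher in the right atrium were the chemokine Ccl7 (3.84), Apoc1 (3.63), the phospholipase Pla2g7 (3.32), the matrix protein Comp (3.31), the integrin Itga8 (3.23), Ahsg (3.09) and Frem1 (3.03). Ccdc3 had 98 counts there and 3 in the remainders, a ratio of 31.3 (exact 95% counting interval 10.4 to 154). Lower were Apln (-3.85), Cldn5 (-3.75), Ly6c1 (-3.70), Rbp7 (-3.69), Ly6a (-3.57), and Prnd (-3.43) and Prn (-3.28), which overlap each other. The protease inhibitor gene Timp4 had 3 counts in the right atrium and 70 in the remainders, a ratio of 24.3 (7.99 to 121).

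Of 13 endocardial genes 7 rose and 0 fell, with 8 and 0 adjusted over the list alone, including Adgrg6 (1.91), Foxc1 (1.70) and Tmem108 (1.45), with camera adjusted p = 1.3e-08 and adjusted p = 0.103 with an estimated correlation. Of 18 capillary and coronary genes 0 rose and 14 fell, with 0 and 15 adjusted over the list alone, including the water channel Aqp1 (-2.27), with camera adjusted p = 4e-29 and adjusted p = 0.129 with an estimated correlation. Among 74 transcription factors 12 rose and 10 fell, with 16 and 19 adjusted over the list alone, and Sox18 (-2.21), Meox2 (-2.52) and Tbx3 (-2.49) were lower. Of 21 fatty acid metabolism genes 0 rose and 14 fell, with 0 and 19 adjusted over the list alone (Fabp3 -4.14; camera adjusted p = 7.8e-21, adjusted p = 0.224 with an estimated correlation). Extracellular matrix genes split, with fibronectin Fn1 (1.97) and periostin Postn (2.46) among 6 of 35 that rose and elastin Eln (-1.70) and Col15a1 (-1.59) among 4 that fell, or 8 and 7 adjusted over the list alone. Of 15 genes of retinoic acid and chamber position 2 rose (Hand2 1.38, Rarb 1.85) and 2 fell (Sfrp1, and Dhrs3 at -1.33), with 5 and 3 adjusted over the list alone. Of 24 dissociation response genes 5 rose and 0 fell, with 9 and 1 adjusted over the list alone, led by Fosb (3.91), Fos (3.62) and Egr1 (3.06; adjusted p = 0.433 with an estimated correlation). Cardiomyocyte RNA moved too, since 18 of 26 sarcomere genes fell and 0 rose, with 23 and 1 adjusted over the list alone (Myl3 -5.95; adjusted p = 0.353 with an estimated correlation). Fabp3, Postn, Sfrp1, Fosb, Fos, Egr1 and Myl3 lay below background here.

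The edgeR test called 831 of 11530 genes, 320 higher and 511 lower in the right atrium, of which 299 and 227 lay above background. In endocardial cells alone, where 1 remainder had at least 20 cells and the 3 right atria were set against that 1 sample, 44 genes passed, 6 higher and 38 lower, among them Irx5 at 3.22 and Cd36 at -1.86, while Npr3, at 1.06, did not pass. Tmem108, at -0.05, and Col15a1, at 0.76, turned and did not pass there. Library-set genes took 9 of the 10 largest increases before they were left out (Rps6 6.41, first set 0.34 to 1.42, adjusted p from 0.14 to 0.87, where tested). The count was 78 without the remainder without the right atrium, 213 without right atrium 3, 1296 with no filter on low counts, 1251 with doublets kept and 384 with thinned counts. With the left atrium added to the remainders, edgeR called 0 genes, and 1069 had an unadjusted p under 0.05.

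**Figure D3:**
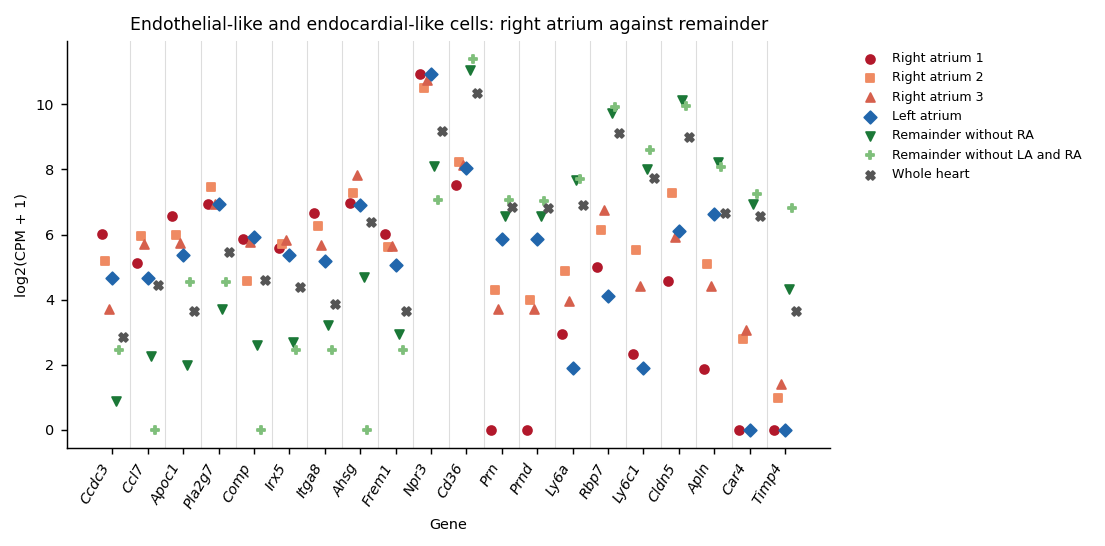
Levels in endothelial and endocardial cells, as log2(CPM + 1), of the 10 genes named as most raised and the 10 named as most lowered in the right atrium, library-set genes left out; each point is 1 biological sample. Npr3 and Irx5 lie higher in the 3 right atria than in both remainders, and Cd36 and Car4 lower.

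Fibroblasts of the right atrium held higher levels of dissociation response genes, with other genes higher and lower. The AP-1 subunit Fosb was higher by a log2 fold change of 4.17 (SE 0.51, adjusted p = 0.000593), at 706 ± 235 CPM (SD, n = 3) against 50.8 ± 36.5 (n = 2). Id4, an inhibitor of basic helix-loop-helix factors, rose by 3.31 (SE 0.49, adjusted p = 0.00193), and Fmo2, a monooxygenase, by 3.15 (SE 0.43, adjusted p = 0.000878), from 45.7 ± 22.0 to 341 ± 78.1 CPM. The surface protein gene Thy1 was lower by -3.16 (SE 0.44, adjusted p = 0.000878), at 10.2 ± 4.09 against 70.4 ± 34.5 CPM, and the ferritin receptor gene Scara5 by -3.60 (SE 0.63, adjusted p = 0.00646). Most right atrial fibroblasts lay in clusters 10 and 16, and most of the remainders' in clusters 14 and 2.

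Also higher were the chemokine Cxcl1 (3.76), the stress factor Atf3 (3.71), Moxd1 (3.53), Angptl7 (3.28), Fam221b (3.20), Btg2 (2.85), the adhesion molecule Sele (2.82) and the Notch target Hey1 (1.78). Also lower were the Notch ligand relative Dlk1 (-2.97), Plekha6 (-2.41), the ectonucleotidase Entpd2 (-2.25), Cd34 (-2.19), the imprinted gene Mest (-2.14), which overlaps Copg2, the guidance factor Sema3c (-2.11), Insig1 (-2.05) and Col26a1 (-2.02). Of 25 dissociation response genes 12 rose and 0 fell, with 22 and 0 adjusted over the list alone, including Jun (2.42) and Egr1 (2.46), with camera adjusted p = 4e-29 and adjusted p = 0.224 with an estimated correlation. Of 77 transcription factors 2 rose and 0 fell, the same counts adjusted over the list alone (Id4, Hey1). Of 36 extracellular matrix genes 0 rose and 3 fell, with 0 and 5 adjusted over the list alone, namely Smoc2 (-1.85), Col8a1 (-1.50) and Fbln5 (-1.47; camera adjusted p = 0.005, adjusted p = 0.379 with an estimated correlation). Of 11 ventricular genes 0 rose and 5 fell, with 0 and 9 adjusted over the list alone, as Myl2 stood at 1468 ± 1577 CPM in the remainders' fibroblasts against 11.4 ± 14.2 (adjusted p = 0.249 with an estimated correlation).

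The edgeR test called 168 of 11294 genes, 90 higher and 78 lower, of which 87 and 35 lay above background. The balance turned to 64 higher and 105 lower in the first library set alone, and to 64 and 91 with library-set genes left out. Of the 10 largest increases 9 were ribosomal library-set genes (Rps27a 5.40), at 0.20 to 1.36 in the first set with adjusted p from 0.13 to 0.96. Without the remainder without the right atrium edgeR called 0 genes, and 707 of 9914 had an unadjusted p under 0.05; without right atrium 1 or 3 it called 52 or 21, and without right atrium 2 it called 264. DESeq2 called 38 genes, thinned counts gave 34, the fit to the compared groups alone 66, at least 1000 UMIs 258, no filter on low counts 354, and the left atrium added to the remainders 1.

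The 1 left atrium was set against the 3 right atria. It is assumed to vary like the other groups, so a difference of side is confounded with that of a single sample. In the first library set alone the left atrium rests on 1 library, so a loss there can come from fewer counts. In cardiomyocytes Sfrp1, a secreted Wnt antagonist, was higher in the left atrium by a log2 fold change of 2.96 (SE 0.39, adjusted p = 0.00655), at 1108 CPM in the 1 left atrium against 142 ± 34.6 (SD, n = 3), and Fhl1, a LIM protein of muscle, by 2.87 (SE 0.27, adjusted p = 0.00115). Bmp10 had 2 counts in left atrial and 8170 in right atrial cardiomyocytes, a ratio of 603 (exact 95% counting interval 167 to 4982). Id2, an inhibitor of basic helix-loop-helix factors, was lower by -3.50 (SE 0.47, adjusted p = 0.00655), at 12.6 against 144 ± 42.4 CPM.

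Other genes higher in this left atrium were Ddit4l (4.78), the protease Adamts8 (3.69), the urotensin gene Uts2b (2.68), the slow skeletal troponin Tnnt1 (2.61), Prss23 (2.51), the noncoding RNA Meg3 (2.00) and skeletal actin Acta1 (1.88). Lower in it were Arpp21 (-3.67), Gsg1l (-3.29), Cacna2d2 (-2.96), the phosphodiesterase Pde1c (-2.86), Thbs4 (-2.33) and Pts (-2.06). The vasodilator peptide gene Adm had 2 counts on the left and 682 on the right, a ratio of 50.4 (13.9 to 417), and Dbh, of noradrenaline synthesis, 1 and 356, a ratio of 52.6 (9.38 to 2082). Of 18 pacemaker and conduction genes 0 rose and 1 fell, with 0 and 9 adjusted over the list alone (camera adjusted p = 1.7e-14, adjusted p = 0.103 with an estimated correlation). In the first library set alone these became 0 and 0, with 0 and 3. Of 42 proliferation genes 0 passed over all genes, and 0 rose and 10 fell adjusted over the list alone (camera adjusted p = 1.1e-15, adjusted p = 0.224 with an estimated correlation). In the first library set alone those 10 became 0 (camera adjusted p = 0.0179). Of 24 dissociation response genes 0 passed over all genes, and 0 rose and 3 fell adjusted over the list alone (camera adjusted p = 6.1e-06, adjusted p = 0.335 with an estimated correlation). Of 13 hypoxia genes 0 rose and 1 fell, with 0 and 4 adjusted over the list alone, or 0 and 2 in the first library set (camera adjusted p = 2.4e-07, adjusted p = 0.131 with an estimated correlation). Among 17 atrial genes 0 rose and 2 fell (Bmp10, Adm), over all genes and adjusted over the list alone. The median of that list was 0.03, its mean -0.94, and camera placed it lower (adjusted p = 0.0011, adjusted p = 0.46 with an estimated correlation).

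The edgeR test called 24 of 12082 genes, 12 in each direction, and 760 had an unadjusted p under 0.05. In the first library set alone 6 passed, and Meg3, at -0.22, did not, while the second set alone gave 71. The count was 42 without right atrium 2, 63 without right atrium 1, 40 without library-set genes, 47 in the fit to the compared groups alone and 142 with no filter on low counts. Over all cells 4 of 15038 genes passed, with 660 at an unadjusted p under 0.05: Ddit4l (4.18), Adamts8 (3.42) and Sfrp1 (2.25) were higher in the left atrium, and Bmp10 was lower, with 3 counts against 9194 and a ratio of 387 (132 to 1878). In the first library set alone edgeR called 0 genes over all cells, and 786 had an unadjusted p under 0.05.

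**Figure D4:**
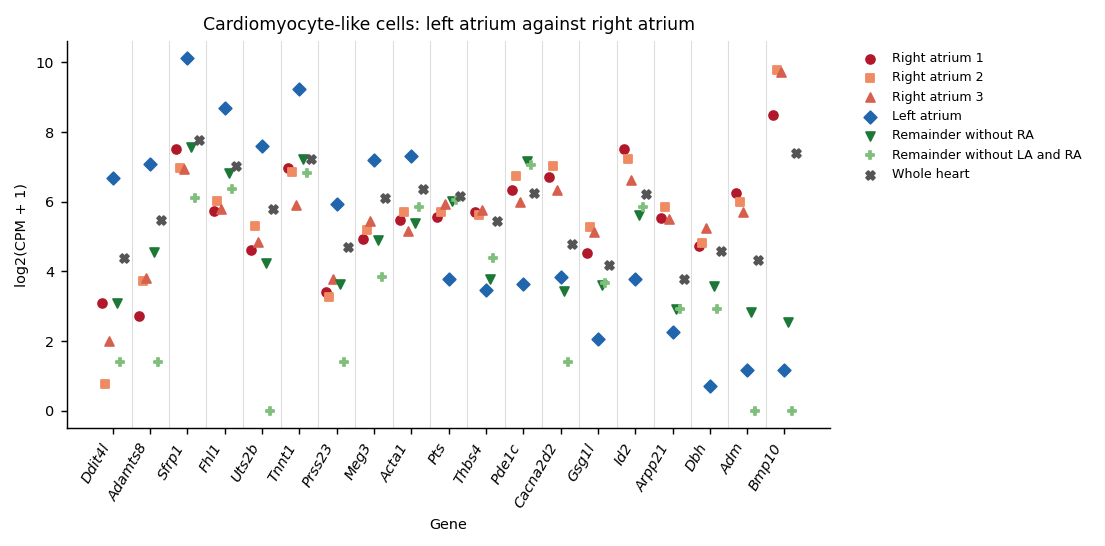
Levels in cardiomyocytes, as log2(CPM + 1), of 9 of the 10 most raised genes and the 10 most lowered in the left atrium against the right; each point is 1 biological sample. Sfrp1 stands at 1108 CPM in the left atrium against a mean of 142 in the right atria, and Bmp10 at 1.26 against 690.

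The reference map was made to choose transcription factors, so each factor's level was set against the mean of the other classes, for 8 classes seen in at least 4 samples. Spi1, the master factor of myeloid cells, was higher in macrophages by a log2 fold change of 9.17 (SE 0.28, adjusted p = 6.65e-30), at 325 ± 139 CPM (SD, n = 5 samples). The epicardial factors Bnc1 and Wt1 were higher in epicardial cells by 8.55 (SE 0.36) and 5.78 (SE 0.23), at 116 ± 50.5 and 339 ± 106 CPM (n = 6). Tcf21, a factor of cardiac fibroblasts, was higher there by 5.99 (SE 0.15, adjusted p = 8.58e-36), at 636 ± 229 CPM (n = 7). Sox17, an arterial endothelial factor, was higher in endothelial cells by 7.13 (SE 0.35), at 201 ± 79.7 CPM (n = 5), and Foxc1 in endocardial cells by 5.05 (SE 0.18), at 175 ± 24.1 CPM (n = 6).

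Macrophages also held the blood factors Ikzf1 (7.77), Cebpa (7.77) and Runx1 (6.26), epicardial cells Gata5 (5.90) and Tbx18 (5.16), and fibroblasts Twist2 (5.59), Sox9 (5.44) and Osr1 (5.31). Endothelial cells held Meox2 (6.08), Sox18 (5.66) and Erg (4.97), and endocardial cells Sox7 (4.65), Foxc2 (4.62) and Erg (4.43). In atrial cardiomyocytes the stretch-responsive Ankrd1 (3.80), the Z-disc protein Csrp3 (3.51) and Tbx5 (3.47, SE 0.14, 355 ± 53.7 CPM, n = 6) were higher. In ventricular cardiomyocytes Irx3 (3.57), Nkx2-5 (3.04, 221 ± 82.0 CPM, n = 4), Hopx (2.95) and Csrp3 (2.85) were higher. A gain over the mean of the other classes does not make a factor particular to 1 class. Nkx2-5 stood at 208 CPM in atrial cardiomyocytes, and Sox7 at 145 CPM in endocardial and 146 in endothelial cells. Osr1 stood at 80.8 CPM in fibroblasts and 73.9 in epicardial cells, while Tcf21 reached at most 96.8 CPM outside fibroblasts. Erythroid cells held the cardiomyocyte genes Ankrd1 (2.72), Csrp3 (2.42) and Nkx2-5 (2.42), with Ankrd1 at 5978 CPM against 11047 in atrial cardiomyocytes. The background rule was not applied to class comparisons, so free RNA or mixed droplets stay open for these genes and for the counts of this class.

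Of 110 factors 82 could be tested, and edgeR called 421 pairs of factor and class over 9340 genes, 231 higher and 190 lower. Each of the 82 was higher in at least 1 class. Endocardial cells had 41 higher and 20 lower factors, or 42 and 22 adjusted over the list alone. Fibroblasts had 39 and 22 (40 and 24 adjusted over the list alone), endothelial cells 35 and 18 (35 and 21) and epicardial cells 28 and 19 (28 and 20). Atrial cardiomyocytes had 25 and 38 (the same adjusted over the list alone), ventricular cardiomyocytes 19 and 41 (the same), erythroid cells 23 and 4 (25 and 6) and macrophages 21 and 28 (21 and 33). In endothelial cells the list's median was -0.07, its mean 0.71, and camera placed it higher (adjusted p = 0.00134, adjusted p = 0.0858 with an estimated correlation).

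**Figure D5:**
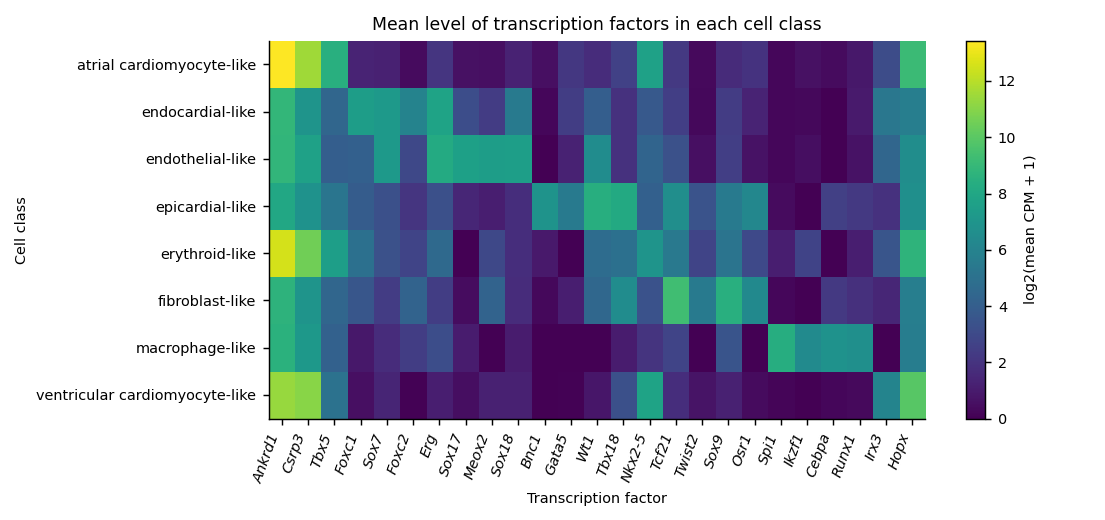
Mean level of each named transcription factor in 8 cell classes, as log2(mean CPM + 1) by colour. Spi1 is brightest in macrophages (325 CPM), Wt1 in epicardial cells (339 CPM) and Tcf21 in fibroblasts (636 CPM).

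Proliferation genes were set against the classes in the same fit. Endothelial cells had 25 of 42 higher and 0 lower, over all genes and adjusted over the list alone, including the mitotic genes Kif23 (1.26, SE 0.23), Plk1 (1.10), Aurkb (1.07) and Tpx2 (1.01), with camera adjusted p = 0.00645 and adjusted p = 0.73 with an estimated correlation. Fibroblasts had 16 higher and 0 lower, over all genes and adjusted over the list alone, led by genes of DNA replication such as Pclaf, Tyms (0.93), Hells (0.92) and Gins2 (0.73; camera adjusted p = 0.334). Endocardial cells had 13 higher and 0 lower (3 and 0 adjusted over the list alone; Tyms 0.84, Smc4 0.83) and macrophages 8 and 0 (6 and 0 adjusted over the list alone; Aurkb 1.44, Kif11 1.22). Atrial cardiomyocytes had 0 higher and 15 lower and epicardial cells 0 and 14, the same counts adjusted over the list alone, with adjusted p = 0.73 and 0.622 with an estimated correlation. Ventricular cardiomyocytes had 3 higher (Rrm2 1.48, Ube2c 0.83, which overlaps the troponin gene Tnnc2, and Kif20a 0.47) and 6 lower, or 1 and 2 adjusted over the list alone, and erythroid cells 0 and 3, or 0 and 1. That gave 65 higher and 38 lower pairs. The 103 pairs became 51 in the first library set alone and 217 at Leiden resolution 0.5, where Ube2c was lower in ventricular cardiomyocytes (-2.01) and Rrm2 and Kif20a did not pass.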

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

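The tests of handling, that of cell type in fibroblasts and the split of the library-set genes by direction were chosen only after the results were seen. In the whole heart 1 technical library had a fibroblast share of 34.69%, while the other 6 lay between 25.6% and 28.6% (gap over range 0.670). It was the 1 library to stand out among 32 groups tested, and chance does this in about 1 of 20 groups.

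The difference between right atrium and remainder itself differed between the sums of cell types when tested as an interaction in edgeR. The cardiomyocyte and endothelial sums pool classes whose shares differ between the pieces, and the background rule was not applied. The counts below can therefore hold cell makeup and free RNA as well as changes within a cell type. It did so for 394 of 11326 genes between endothelial and fibroblast cells, of which 3 were called in both with opposite signs (Rgs5, Dpp4 and Thsd4). Between cardiomyocytes and fibroblasts it differed for 351 of 12260 genes, with 4 of opposite sign (Mest, Copg2, Rgs5 and Hs6st2). Between cardiomyocytes and endothelial cells it differed for 524 of 12317 genes, with 13 of opposite sign. One of these is Irx5, lower in right atrial cardiomyocytes (-4.41) and higher in right atrial endothelial cells (3.24). These genes were named after their values were seen.

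The first pattern weighed is the set of 1379 genes that separate right atrial cardiomyocytes from those of the remainders, since only the atria have libraries of the second set. In the first set alone 99.55% of the 1329 called genes tested there kept their sign, the median ratio of the changes was 1.01, and 1005 passed again, which argues against the mix of sets as the whole cause. Of the 105 called genes that also differ between the sets, 94.29% kept their sign with a median ratio of 0.58, which leaves them open as a whole. The 70 of these that were higher in the right atrium kept a median of 0.22 of their change, in line with the library sets as a source, while the 35 lower ones kept 1.1 times it, which argues against that source. A chamber difference stays an open explanation for the rest.

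The second pattern is the rise of dissociation response genes in the right atrium. In cardiomyocytes no source can be told apart, because few of these genes reached their level over all cells, so free RNA from other cells can set their levels. Within the remainder without the right atrium the median log2 ratio of atrial to ventricular cells was -0.03, where 4 and 2 of 25 genes reached that level. Within ventricular cells the whole heart stood above that remainder by a median of 0.85, where 0 and 2 did. In fibroblasts all 25 genes tested lay above background, and the list's median log2 fold change in the right atrium was 1.90 (quartiles 1.33 to 2.42, 24 of 25 genes). The rise was thus not limited to muscle cells. Its size in fibroblasts was known when this test was chosen, so the test weighs no cause. Handling that differed between dissected pieces may contribute, since within fibroblast cluster 14 the whole heart stood above the remainder without the right atrium by a median of 2.18 (quartiles 0.95 to 3.35, 23 of 25 genes, 278 and 218 cells). That rests on 1 sample of each, so a difference between the animals was not tested and stays open.

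The third pattern is the set of clusters led by protocadherin or Ugt1a genes, 2 of which stayed unnamed. In the median cell with a count in such a family, 100% of its genes had the same count, consistent with 1 read being counted for every gene that shares an exon, against 4.55% in the Pcdhb genes, of which 3 of 22 have overlapping exons. When the 3 families were left out of the clustering, the cluster that took most of the 390 unnamed cells held 27.95% of them, which argues against a cell type of their own. Of these cells 52.3% then fell among atrial and 28.2% among ventricular cardiomyocytes. No other biological explanation was tested.

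Class labels were shuffled within each sample 20 times. For transcription factors 1 of 21 draws, the real one, gave as many called pairs (421, against 22 at most in the others). For proliferation genes it was again 1 of 21 (103 pairs, against 0 in the others). Shuffled labels did not reach either count, and 20 shuffles allow no share below 1 of 21. The classes were made from the same cells, so the shuffles do not show how much of either count the clustering itself creates.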

How the results depend on the processing

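The alternatives that used the first or second library set alone, left out library-set genes, merged barcodes, left out gene families from the clustering, took endocardial cells alone or left out cluster 7 were chosen after the data were seen. The other settings, the estimated correlation and fry included, were fixed before. No paired analysis was possible because the groups compared share fewer than 2 replicate numbers. Where a left-out sample leaves 1 sample in a group, that sample is assumed to vary like the other groups.

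The 364 pairs of named gene and comparison gave 7237 values under alternatives. Of these 6231 kept direction and threshold, 996 kept the direction and lost the threshold and 10 turned. Adding the left atrium to the remainders lost 278, leaving out the remainder without the right atrium 182, right atrium 3 105 and the other remainder 81. The first library set lost 68, DESeq2 52 (and gave 6 values no adjusted p), endocardial cells alone 52, and thinned counts 47. Of 162 share values 149 stayed within 1 SD, 8 moved further and 5 turned. The samples did not overlap for 8 of 10 classes, and under alternatives for 7 to 9 of the 9 to 11 classes found.

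Counts of called genes outside 1.5 times the reported ones follow. With no filter on low counts they were 1827 (922 higher, 905 lower) over all cells, 354 in fibroblasts, 1296 in endothelial cells, and 142 and 156 for left against right atrium in cardiomyocytes and all cells, where more genes are tested. With the left atrium added to the remainders they were 3 over all cells, 16 (13 higher, 3 lower) in cardiomyocytes, 1 in fibroblasts and 0 in endothelial cells (edgeR, 1069 at an unadjusted p under 0.05). Leaving out 1 sample gave 39 to 1037 over all cells, 580 to 1404 in cardiomyocytes, 0 to 264 in fibroblasts and 78 to 826 in endothelial cells. It gave 17 to 63 for left against right atrial cardiomyocytes and 2 to 18 over all cells. The lowest count of the first 4 came without the remainder without the right atrium, where fewer samples are left; in fibroblasts 707 genes had an unadjusted p under 0.05. DESeq2 gave 38 in fibroblasts, 462 in endothelial cells and 21 for left against right over all cells. Thinned counts gave 791 in cardiomyocytes, 34 in fibroblasts and 384 in endothelial cells. A minimum of 1000 UMIs gave 258 in fibroblasts, and doublets kept 1251 in endothelial cells. The fit to the compared groups alone gave 66 in fibroblasts and 47 for left against right atrial cardiomyocytes. For left against right, the first set gave 6 in cardiomyocytes and 0 over all cells (edgeR, 786 unadjusted), the second set 71 and 34, and leaving out library-set genes 40 and 7. Endocardial cells alone gave 44 (6 higher, 38 lower), with 1 remainder left. Proliferation pairs were 217 at Leiden resolution 0.5, 51 in the first set, 187 with barcodes merged and 173 without the gene families, and 75 to 107 with 1 sample left out. Factor pairs stayed within 315 to 473. Of 114 list tests 69 passed with camera's preset correlation and 61 when run in the first set alone. With an estimated correlation 0 passed (limma, 23 unadjusted), with fry for one direction 18 and with fry for either direction 65. Fewer samples or counts can lower the left-out and thinned counts by construction. The left atrium holds 54.6% atrial and 0% ventricular cardiomyocytes. Adding it to the remainders puts a piece led by atrial cardiomyocytes on both sides, which can lower those counts by construction too. The cause of the rises and of the remaining shifts was not tested.

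Values that turned are these. The unnamed share difference was 6.25 percentage points at 1000 UMIs, 2.15 with doublets kept, 2.68 at resolution 2.0, 3.32 with barcodes merged and 2.85 without the gene families. With the left atrium added, Gapdh was at -0.32 and Rps12 at -0.14 in cardiomyocytes. There the mix of library sets changes, since the left atrium has 4 libraries in the second set and the remainders have 0. Nppb was at 6.87 in fibroblasts without the remainder without the right atrium, and at -3.09 without the remainder without either atrium. In endocardial cells alone Cited2 was at -0.002, Col15a1 at 0.76 and Tmem108 at -0.049. Meg3 was at -0.22 in the first set for left against right. Rrm2 was at -0.21, Ube2c at -2.01 and Kif20a at -0.31 in ventricular cardiomyocytes at resolution 0.5. The cause of these was not tested. Depth limits the smaller samples most, since the remainder without either atrium holds 268 barcodes and 1145477 counts.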

Other observations

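All tests and values here were chosen after the data were seen. Among atrial cardiomyocytes, cluster 7 (109 cells) held genes of the sinoatrial node. Against the other atrial cardiomyocytes of the same 4 samples with at least 10 such cells, edgeR called 12 genes higher and 38 lower of 9257. Shox2, a factor of the sinus node, was higher by a log2 fold change of 3.31 (adjusted p = 1.4e-08), at 92.2 ± 104 CPM (SD, n = 4 samples, so with a wide spread), Tbx3, which represses working muscle genes in the conduction system, by 2.19 (adjusted p = 0.0362) and Id2 by 0.83 (adjusted p = 0.0194). Of 43 transcription factors tested 3 were higher, and of 15 pacemaker and conduction genes 3 were higher. Shox2, Tbx3 and Id2 belong to the factor list, which was left out of the clustering genes.

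Dissociation response genes summed to 8550, 16086 and 14768 CPM in fibroblasts of right atria 1, 2 and 3, to 4843 and 2621 CPM in those of the remainders, to 13405 CPM in the whole heart and to 9888 CPM in the left atrium. Cluster 17, epicardial by its markers (344 cells), was led by the airway genes Scgb3a2, Scgb3a1 and Scgb1a1, although 0.581% of its cells had a count of Scgb1a1. Over all barcodes Scgb1a1 stood at 59.8 CPM in the remainder without the right atrium and 24.1 CPM in the whole heart. The neural crest and surface ectoderm factor Tfap2a stood at 50.0 CPM in atrial cluster 6. Clusters 4 and 15, ventricular and atrial by their markers, were led by cell-cycle genes such as Anln and Spc25, although the proliferation list was left out of the clustering.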
